A study of Mus musculus with 6 samples.

How the data were processed

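The samples were mouse embryonic stem cells, 3 with a control transfection and 3 with an shRNA vector against Chd9, each measured on 1 Illumina bead array. Groups were taken from the transfection named in the labels. Replicates were numbered in the order of the deposit, and the labels do not pair the samples.

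The deposited non-normalized table holds, per the file headers, an average intensity and a detection p-value for each of 45281 probes on each array. The intensities are on a linear scale, and the values show neither normalization between arrays nor background subtraction, with a lowest value between 75.4 and 90.9 per array. The authors' deposited p-value says how far a probe lies above the array's negative control beads. GenomeStudio is named in the submitters' processing notes, with no version or settings given. The deposited series table holds a second intensity per probe, on a linear scale with no centring. Its values were found to be the raw intensities quantile normalized to the mean of the sorted arrays (largest difference 0.690), with a rank correlation of 1 with the same array and of at most 0.814 with any other array. The column medians of that table were 111.400, 111.389, 111.397, 111.377, 111.385 and 111.368 in the order control 1 to 3 and shChd9 1 to 3.

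Gene names came from GEO's annotation table of the platform, updated through Entrez identifiers with a RefSeq gene table (GRCm38.p6). Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, and the last 2 kinds were tested but not named. No genome was used, and no probe positions are given.

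Intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function corrected the background by the normal-exponential model, with the negative controls inferred from the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. Quantile normalization assumes that most probes do not differ between arrays, and removes any overall difference. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested, which left 17719 probes, 15333 of them with 1 symbol. Each of the 10194 genes was represented by its probe with the highest mean over all arrays. Of 3647 genes with several tested probes, 1619 had log2 fold changes of both signs, among the genes named in the text Actb, Bcl2l11, Chd1, Chd4, Chd9, Pecam1, Rap2a and Rrm1. The groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probes or all genes and a threshold of 0.05. Values are log2 fold changes of shChd9 over control with moderated SE and 95% intervals, and group means are given with the SD of 3 arrays. An exact two-sided permutation test over the 10 splits of the arrays, which cannot go below p = 0.10, was run for each Chd9 probe, each list mean and the number of detected probes. A gene not detected on any array of a group was given a bound, the other group's mean over the higher of the lowest detected signal and the gene's own signal on each array. This bound concerns detection only and leaves out the spread between arrays.

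The text names genes by a rule fixed before the data were examined, as were the gene lists and the main tests of probes, genes and lists. It takes every Chd9 probe, and in each direction the 14 genes with the largest fold change among those past the threshold whose groups do not overlap. Where fewer than 5 pass, it takes the 10 with the smallest p in that direction. For each list it takes up to 4 members past the threshold, or, where none passes, up to 2 with the smallest p. It adds the CHD family and Actb, Gapdh, Hprt and Tbp. The 38 gene lists cover pluripotency, lineages, other cell types, chromatin, growth, metabolism and stress, and 975 of their 985 entries matched a gene of the array. The 36 lists with at least 5 measured members were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists, and members were also adjusted over the list alone. The same lists were tested with camera's estimated correlation and with fry, which tests whether a list's genes move on balance one way.

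The tests were tested on simulated data with the means and spreads of the real probes. Among 17719 simulated probes, 50 each were changed by 1.5-, 2-, 3- and 4-fold, and limma recovered 20%, 70%, 98% and 100% of them, with 12 of the 17519 unchanged probes called. Of the simulated gene lists, the 1 shifted list was found and 0 others were called. The simulated genes varied independently, whereas the list of feeder fibroblast markers had an estimated correlation of 0.51. False list calls under such correlation were therefore not tested. Raw mean intensities were between 356 and 464 per array and between 39.2% and 40.8% of probes were detected on each array. Signal over background limits what can be seen of dim genes, and 3 arrays per group limit the precision.

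Alternatives fixed beforehand were no background correction, normexp without controls (offset 50), median scaling, cyclic loess, the authors' processed values, no filter on dim probes, a stricter filter (detection p-value under 0.01 on all 6 arrays), an intensity trend with a robust prior, array weights, leaving out each array in turn, the mean of a gene's probes, and thresholds of 0.01 and 0.1. Added after seeing the data were the arrays paired by their shared deviations as a block, the mean of the feeder markers as a covariate, the lists without their feeder markers, and the exact test of list means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 1 slide holds all arrays, so there was no slide effect to test. No sample was left out.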

Results

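Gene expression was measured in mouse embryonic stem cells that had received a short hairpin RNA (shRNA) vector against Chd9, referred to as shChd9, or a control transfection. Chd9 belongs to the chromodomain helicase DNA-binding (CHD) family, ATP-driven enzymes that act on nucleosomes, and the study addresses what such remodellers do in stem cells. The cells grew with serum and leukemia inhibitory factor, which holds them undifferentiated, on a feeder layer of embryonic fibroblasts whose division had been blocked with mitomycin C. Puromycin, which kills cells without the vector's resistance gene, was given from 24 h after electroporation for 48 h. RNA from 3 control and 3 shChd9 samples was labelled with biotin and hybridised to Illumina bead arrays of 45281 probes, with 1 array per sample and all 6 on one slide. The arrays of each group lay side by side, so that slide position and group cannot be told apart. The labels do not say whether the samples came from separate cultures, and the p-values then measure only the spread between these samples, which may be technical.

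Probes detected numbered 18383, 18457 and 17981 on the control arrays and 18176, 18272 and 17734 on the shChd9 arrays (exact permutation test, two-sided, p = 0.50). Mean raw intensities ranged from 356 to 464. Log2 intensities correlated across probes with r between 0.973 and 0.988 for every pair of arrays, with a median of 0.983 within groups and 0.985 between groups. The first principal component held 36.1% of the variance and the groups overlapped on it, with control scores from -14.1 to 30.6 and shChd9 scores from -35.2 to 13.9. The number of arrays, 3 per group, limits the precision of every value given here.

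Chd9 transcript was lower in the shChd9 cells on both of its well-detected probes, which left 46.3% and 45.8% of the control level. Probe ILMN_1235114 measured 7.62 ± 0.07 in control and 6.51 ± 0.21 in shChd9 cells (log2 intensity, mean ± SD, n = 3 each), a 2.16-fold lower level with a 95% interval of 1.67 to 2.79. Probe ILMN_2697954 measured 7.63 ± 0.24 and 6.51 ± 0.17, a 2.18-fold lower level with an interval of 1.65 to 2.89. On both probes each shChd9 array lay below each control array, and they ranked 1 and 2 by p among the 17719 probes tested. The dim probe ILMN_1226311, detected on 2 control and 3 shChd9 arrays, had a log2 fold change of 0.35 with an interval of -0.12 to 0.81. Probe ILMN_2600528 was detected on 1 array and was not tested. Where these probes lie along the transcript was not analysed here. Adjusted over the 3 tested Chd9 probes alone, limma gave an adjusted p of 0.000196 for each of the first 2 probes and 0.125 for the dim one, while over all probes tested its adjusted p was 0.540, 0.540 and 0.925. The exact two-sided permutation p was 0.10 for each of the first 2 probes, the smallest that 3 against 3 allows. Without background correction their log2 fold changes were -0.66 and -0.68, against -1.11 and -1.13 with it.

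**Figure D1:**
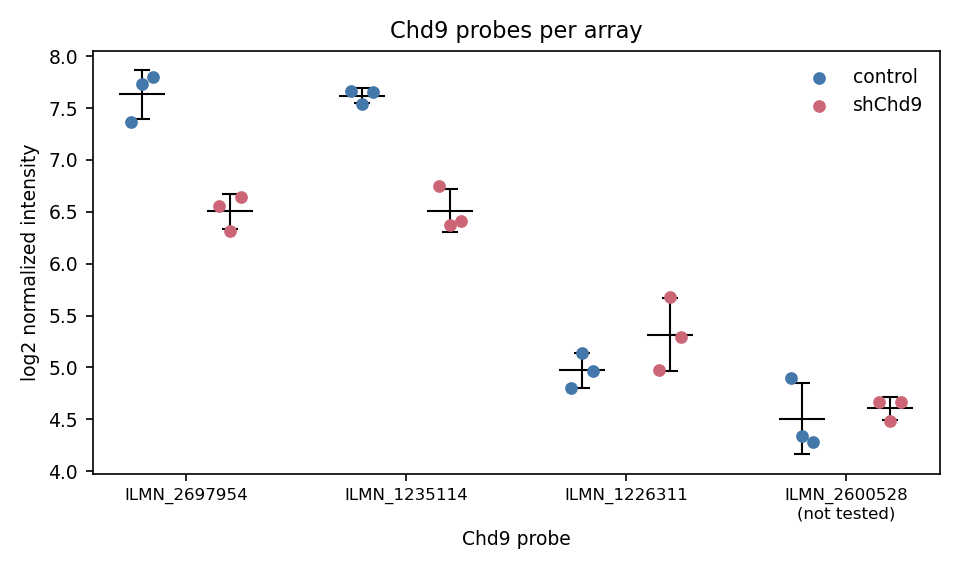
Log2 normalized intensity (vertical axis) of the 4 Chd9 probes (horizontal axis) on each control (blue) and shChd9 (red) array, with the group mean as a horizontal line and the SD as an error bar (n = 3). The 2 brighter probes lie between 7.36 and 7.80 in control and between 6.32 and 6.75 in shChd9 cells, and the 2 dim probes do not separate the groups.

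No gene passed the test after adjustment over all genes, Chd9 included (limma, adjusted p = 0.389). The other genes with the smallest p included Krt17, a keratin, with a log2 fold change of -0.96 ± 0.15 (SE), Zscan5b, a zinc finger gene, with -1.21 ± 0.20, and Myl4, a myosin light chain, with -0.93 ± 0.15, at an adjusted p of 0.389 (limma, n = 3 each). The uncharacterised BC052688 measured -1.15 ± 0.20 at 0.454, and Bcas1 measured -0.81 ± 0.15 at 0.769. The homeodomain-only gene Hopx measured -1.15 ± 0.23, Serpinb6c, a serine protease inhibitor, -0.95 ± 0.20, Fam25c -0.80 ± 0.17, and Aurkc, a meiotic Aurora kinase, -1.14 ± 0.25, each at 0.924. In the other direction stood Col4a2, a basement membrane collagen, with 0.90 ± 0.19, Col10a1, a collagen of hypertrophic cartilage, with 0.93 ± 0.22, Fam177a with 0.87 ± 0.20 and the small GTPase Rap2a with 0.73 ± 0.19 (its dimmer probe ILMN_1220553 gave -0.20). The dimmer Fam177a probe ILMN_3034034 gave 0.32. The imprinted non-coding RNA Peg13 measured 0.66 ± 0.16, Stk36 0.67 ± 0.16, 4930402H24Rik 0.62 ± 0.15 and the endothelial adhesion gene Esam 0.61 ± 0.16. The sulfotransferase Chst5, near background and detected on 1 control array, measured 0.66 ± 0.17. All of these genes higher in shChd9 cells had an adjusted p of 0.924, as did Nmnat2, an enzyme of NAD synthesis. Nmnat2 was not detected on any control array and measured at least 1.13-fold higher in shChd9 cells. This bound was taken against the lowest detected signal of each control array and leaves out the spread between arrays. These genes were the 10 with the smallest p in each direction, Chd9 itself being one of the lower ones. In each of them the groups did not overlap.

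At an adjusted p under 0.05, limma called 0 of 17719 probes and 0 of 10194 genes. At an unadjusted p under 0.05 it found 942 probes, 417 higher and 525 lower in shChd9 cells, where 886 would be expected by chance. By gene these were 524, 226 higher and 298 lower, where 510 would be expected. The groups did not overlap in 1069 genes, which is 10.5% against the 10% that chance gives. The 95% interval of the fold change lay within 2-fold in either direction for 9490 genes, or 93.1%, with a median SE of 0.19 on the log2 scale. In simulated data with the same spread, the test recovered 20% of probes changed 1.5-fold, 70% of those changed 2-fold and 98% of those changed 3-fold. Those data held 50 probes at each of these changes and 50 at 4-fold, and drew every probe independently. With fewer changed probes the recovery may be lower. Chd9 probe ILMN_1235114, 2.16-fold lower, had an adjusted p of 0.540 over all probes (limma).

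Other CHD family members and common reference genes were described by their values, since none passed the test (limma, adjusted p at least 0.954). Chd1l measured -0.43 ± 0.25, Chd1 -0.21 ± 0.18, Chd5 -0.17 ± 0.30, Chd2 -0.10 ± 0.19 and Chd6 -0.07 ± 0.20 (log2 fold change ± SE), the last 0.00 under median scaling. Chd8 measured 0.06 ± 0.16, Chd4 0.11 ± 0.16 and Chd3 0.18 ± 0.17. As a list, the 8 measured members averaged -0.08, at an adjusted p of 0.720 in limma's camera test. Actb measured 0.18 ± 0.15, Gapdh 0.10 ± 0.15, Tbp -0.20 ± 0.16 and Hprt 0.32 ± 0.36, the last with an SD of 0.59 in control and 0.64 in shChd9 arrays.

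Fibroblast genes, which mark the feeder layer, were the gene list that stood highest in the shChd9 samples. All 28 measured markers had a positive log2 fold change, with a mean of 0.39, and camera called the list higher with a preset correlation (adjusted p = 2.24e-07). The adjusted p was 0.863 with an estimated correlation. The mean was 0.12 without shChd9 replicate 1, 0.15 without control replicate 2, 0.59 without control replicate 1 and 0.63 without shChd9 replicate 2, each time with the remaining arrays normalized anew. Timp3, an inhibitor of matrix proteases, measured 0.52 ± 0.21 and the calcium-binding S100a4 0.59 ± 0.25 (log2 fold change ± SE). The S100a4 probe was near background, detected on 1 control and 2 shChd9 arrays. None of the 28 passed over all genes tested, and 0 passed adjusted over the list alone, while 4 had an unadjusted p under 0.05 in limma. The mean of the markers on each array was 9.0, 8.1 and 8.6 in control and 9.5, 8.5 and 9.0 in shChd9 samples (log2 intensity), so that the groups overlapped (exact permutation test, unpaired and two-sided, p = 0.50).

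In all, camera called 8 of the 36 lists tested at an adjusted p under 0.05 with a preset correlation, 7 higher and 1 lower in shChd9 cells. With an estimated correlation it called 0, with 2 lists at an unadjusted p under 0.05, and limma's fry called 0, with 1 such list. Without shChd9 replicate 1, which had the highest feeder marker mean, camera called 0 lists with the preset correlation too. Without control replicate 2, which had the lowest, it called 4, and without shChd9 replicate 2 it called 13.

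Markers of the first embryonic lineages outside the epiblast lay higher in the shChd9 samples as groups, in the same samples in which the feeder markers averaged 0.39 higher. Of 16 measured primitive endoderm genes 15 were higher, with a mean log2 fold change of 0.31 (camera, adjusted p = 1.84e-04, and adjusted p = 0.863 with an estimated correlation). Col4a2 was the 1 member to pass adjusted over the list alone (limma, adjusted p = 0.0175), against 0 over all genes tested, and Krt18, a keratin of simple epithelia, measured 0.71 ± 0.23. The list mean was 0.21 without shChd9 replicate 1 or control replicate 2 and 0.49 without shChd9 replicate 2. Of 12 trophectoderm genes 8 were higher, with a mean of 0.29 (adjusted p = 0.00696, and adjusted p = 0.863 with an estimated correlation), and of 0.17 without shChd9 replicate 1. Gata3, a transcription factor of the trophoblast, measured 0.60 ± 0.23, and Krt18 belongs to this list too. The exact permutation p of the list means was 0.20 for primitive endoderm and 0.10 for trophectoderm.

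Hox genes and genes of epithelial adhesion and the epithelial-mesenchymal transition were also called higher with the preset correlation, again beside feeder markers that averaged 0.39 higher. Of 13 Hox genes, which set positions along the body axis, 12 were higher with a mean of 0.24 (camera, adjusted p = 0.0292, and adjusted p = 0.863 with an estimated correlation). The mean was 0.13 without shChd9 replicate 1 and 0.33 without control replicate 3. Hoxa5 measured 0.57 ± 0.28 and Hoxd10 0.39 ± 0.21. Of 19 adhesion and transition genes 11 were higher with a mean of 0.18 (adjusted p = 0.0413, and adjusted p = 0.863 with an estimated correlation), among them the transcription factor Zeb1 at 0.38 ± 0.15. Its mean was 0.08 without shChd9 replicate 1 or control replicate 2, 0.28 without control replicate 1 and 0.30 without shChd9 replicate 2. This list holds feeder markers and was no longer called once they were taken out. In neither list did any gene pass over all genes tested or adjusted over the list alone.

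Signal-response genes were called higher too, with feeder markers 0.39 higher in the same samples. Of 24 immediate early genes, which growth factors and stress induce within minutes, 18 were higher with a mean of 0.18 (camera, adjusted p = 0.00696, and adjusted p = 0.731 with an estimated correlation). The immediate early mean ranged from 0.14 to 0.21 with an array left out, and the exact permutation test gave p = 0.10. With the feeder marker mean as a covariate, a fit added after seeing the data, the immediate early mean was 0.13 ± 0.04 (SE). Spry4 and Dusp6, both feedback inhibitors of ERK signalling, measured 0.47 ± 0.20 and 0.40 ± 0.17. Of 20 targets of the tumour suppressor p53, 17 were higher with a mean of 0.17 (adjusted p = 0.0266, and adjusted p = 0.863 with an estimated correlation). The p53 list mean was 0.10 without control replicate 2, 0.11 without shChd9 replicate 3 and 0.25 without control replicate 3. The cell cycle inhibitor Cdkn1a measured 0.61 ± 0.29 and Phlda3, an inhibitor of Akt signalling, 0.46 ± 0.21. No member of either list passed over all genes tested or adjusted over the list alone.

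Mitosis genes were the 1 list called lower, in samples whose feeder markers averaged 0.39 higher. Of 23 measured members 19 were lower, with a mean log2 fold change of -0.14 (camera, adjusted p = 0.0150, and adjusted p = 0.863 with an estimated correlation). The mean was -0.08 without control replicate 2 and -0.20 without shChd9 replicate 2. Kif11, the spindle motor, measured -0.30 ± 0.20 and Birc5, a subunit of the chromosomal passenger complex, -0.23 ± 0.15. None passed over all genes tested or adjusted over the list alone, and 0 had an unadjusted p under 0.05 in limma.

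**Figure D2:**
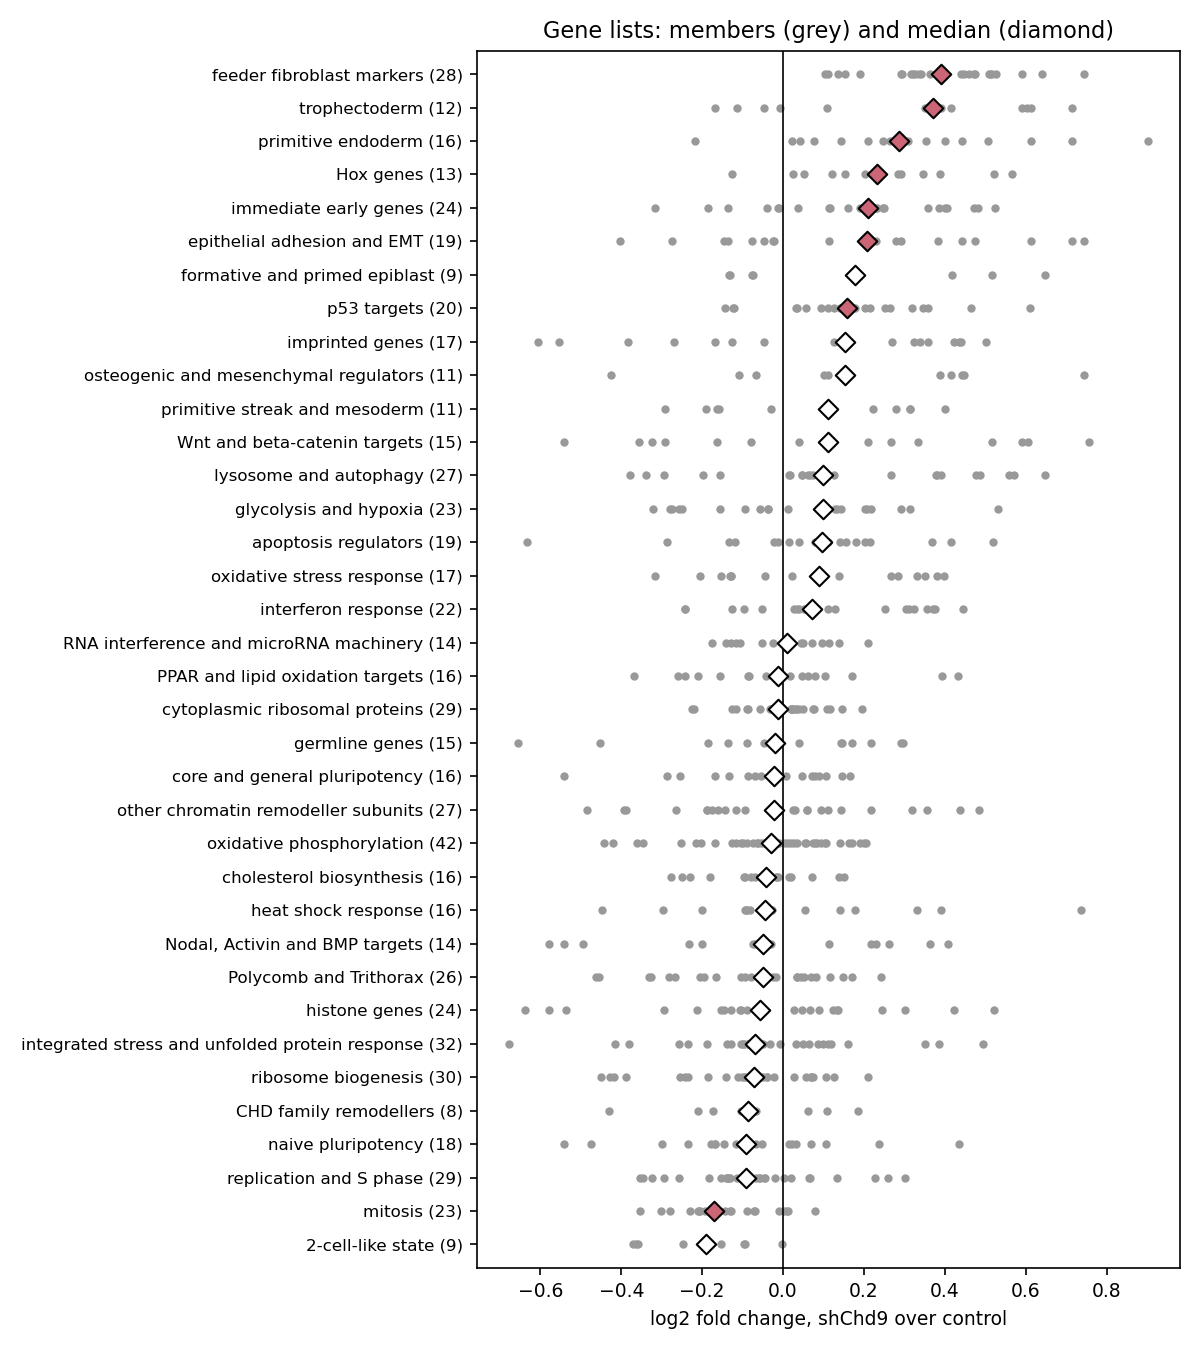
Log2 fold change of shChd9 over control (horizontal axis) of the measured members (grey points) of the 36 tested gene lists (vertical axis, number measured in brackets), with each list's median as a diamond. Red diamonds mark the 8 lists called by camera with a preset correlation, of which the 28 feeder markers all lie above 0; none of the 8 was called with an estimated correlation.

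No list of pluripotency genes or of the signals that act on it was called. The 16 measured core pluripotency genes averaged -0.06, with 8 higher and 8 lower (camera, adjusted p = 0.710), and included Nanog at -0.29 ± 0.18 and the Nodal co-receptor Tdgf1 at -0.54 ± 0.25. The 18 naive pluripotency genes averaged -0.08 (adjusted p = 0.407), with the adhesion gene Jam2 at -0.54 ± 0.19 and Tcl1 at -0.30 ± 0.18. Genes of the formative and primed epiblast averaged 0.17 over 9 members (0.432), with Pou3f1 at 0.42 ± 0.23 and Wnt8a, detected on 2 control arrays, at 0.52 ± 0.29. Genes of the 2-cell-like state were lower in 9 of 9 members with a mean of -0.21 (0.356), with Zscan4c at -0.36 ± 0.42 and Tcstv3 at -0.37 ± 0.46. Without shChd9 replicate 1 Zscan4c was 0.09 and Tcstv3 0.16. With the feeder marker mean as a covariate, a fit added after seeing the data, the list mean was 0.02 ± 0.49 (SE). That value is too imprecise to say whether the lower level goes with the feeder markers. Among Nodal, Activin and BMP targets, which averaged -0.05 (0.726), Lefty1 and Lefty2, both secreted Nodal inhibitors, measured -0.58 ± 0.17 and -0.49 ± 0.19. Wnt and beta-catenin targets averaged 0.11 (0.645), with Cdx1 at 0.76 ± 0.37. No member of these lists passed adjusted over the list alone.

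Lists of chromatin, RNA-silencing, imprinted and germline genes were not called. The 26 Polycomb and Trithorax genes averaged -0.08 (camera, adjusted p = 0.263), with the Polycomb subunits Mtf2 at -0.45 ± 0.16 and Ezh2 at -0.46 ± 0.20. Dimmer Mtf2 probes gave -0.24 and -0.20. The 27 other remodeller subunits averaged -0.01 (0.914), with Smarce1 at 0.44 ± 0.17 and Pbrm1, both of BAF-type complexes, at -0.39 ± 0.18. Histone genes averaged -0.04 (0.781), with H3c3 at -0.58 ± 0.20 and H1f5, detected on 1 shChd9 array, at -0.64 ± 0.28. The RNA interference and microRNA machinery averaged 0.00 (0.982), with Tarbp2 at 0.21 ± 0.15 and Xpo5 at -0.18 ± 0.15. Imprinted genes averaged 0.07 (0.453), with Peg10 at 0.50 ± 0.18. Usp29, not detected on any shChd9 array, measured at least 1.25-fold lower there before allowing for spread (limma, adjusted p = 0.924). Germline genes averaged -0.02 (0.907), with the meiotic gene Tex11, detected on 2 shChd9 arrays, at -0.66 ± 0.28 and Rhox5 at 0.30 ± 0.20. No member of these lists passed adjusted over the list alone.

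Growth and metabolism lists were not called either. Ribosome biogenesis averaged -0.10 over 30 genes (camera, adjusted p = 0.180), with Tcof1 at -0.43 ± 0.24. Rrs1, not detected on any shChd9 array, measured at least 1.19-fold lower there before allowing for spread (limma, adjusted p = 0.954). Replication and S phase genes averaged -0.07 over 29 (0.243), with Chaf1b at -0.35 ± 0.15 and Rrm1 at -0.32 ± 0.17. Cytoplasmic ribosomal proteins averaged 0.00 over 29 (0.978), with Rpl19 at -0.22 ± 0.16 and Rpl6 at -0.22 ± 0.16. The Rpl6 probe was near background, at 4.99 in control against 13.44 for its list (log2 intensity), and was detected on 1 shChd9 array. Oxidative phosphorylation averaged -0.04 over 42 (0.645), with Cox7b at -0.44 ± 0.17 and Cox6c at -0.42 ± 0.20. Glycolysis and hypoxia averaged 0.03 (0.710), with Hk1, detected on 2 control arrays, at 0.53 ± 0.21 and Aldoc at -0.32 ± 0.17. Cholesterol biosynthesis averaged -0.06 (0.567), with Lss at -0.28 ± 0.16 and Stard4 at -0.23 ± 0.17. PPAR and lipid oxidation targets averaged -0.01 (0.978), with Acadvl at 0.43 ± 0.18 and Lpl at -0.37 ± 0.18. No member of these lists passed adjusted over the list alone.

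Stress, death and immune lists gave the following values. Lysosome and autophagy genes averaged 0.14, with 22 of 27 higher (camera, adjusted p = 0.0972), among them the protease Ctsl at 0.57 ± 0.17 and Atp6ap1 at 0.56 ± 0.22. The interferon response averaged 0.12 (0.268), with Ccl5 at 0.45 ± 0.34 and Ifi35 at 0.32 ± 0.23. Apoptosis regulators averaged 0.07 (0.453), with the BH3-only members Bmf at -0.63 ± 0.16 and Bcl2l11 at 0.52 ± 0.16. Dimmer Bcl2l11 probes gave 0.12 and -0.02. The integrated stress and unfolded protein response averaged -0.04 (0.567), with the serine synthesis enzyme Psat1 at -0.42 ± 0.17 and the chaperone Hspa5 at -0.68 ± 0.26. The Hspa5 probe was near background, detected on 2 shChd9 arrays. The heat shock response had a mean of 0.03 and a median of -0.04, with camera's direction lower (0.852). It held Cryab at 0.74 ± 0.26 and Dnaja1, near background and detected on 1 shChd9 array, at -0.45 ± 0.18. Oxidative stress genes averaged 0.07 (0.591), with Slc7a11 at 0.35 ± 0.24 and Txn1 at -0.32 ± 0.23. No member of these lists passed adjusted over the list alone, where the smallest p was 0.0514, for Bmf.

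Markers of other cell types were measured as well. Osteogenic and mesenchymal regulators averaged 0.20 over 11 genes (camera, adjusted p = 0.131), with Sparc, a matrix protein, at 0.44 ± 0.20 and the feeder marker Twist1 at 0.74 ± 0.38. Primitive streak and mesoderm genes averaged 0.07 over 11 (0.710), with Snai1 at 0.28 ± 0.19 and Mixl1 at 0.31 ± 0.25. The Mixl1 probe was near background, with a mean log2 intensity of 4.68. Neuroectoderm had 4 measured members, too few for the list test, with Crabp2 at 0.29 ± 0.16 and Nes at 0.33 ± 0.21. Serum and haematopoietic markers had 3, with Cd14 at 0.19 ± 0.41 and Pecam1 at -0.13 ± 0.32. No member of these lists passed adjusted over the list alone. The median and mean of a list differed in sign for the heat shock response and for the RNA interference and microRNA machinery, and camera's direction differed from the sign of both for germline genes.

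**Figure D3:**
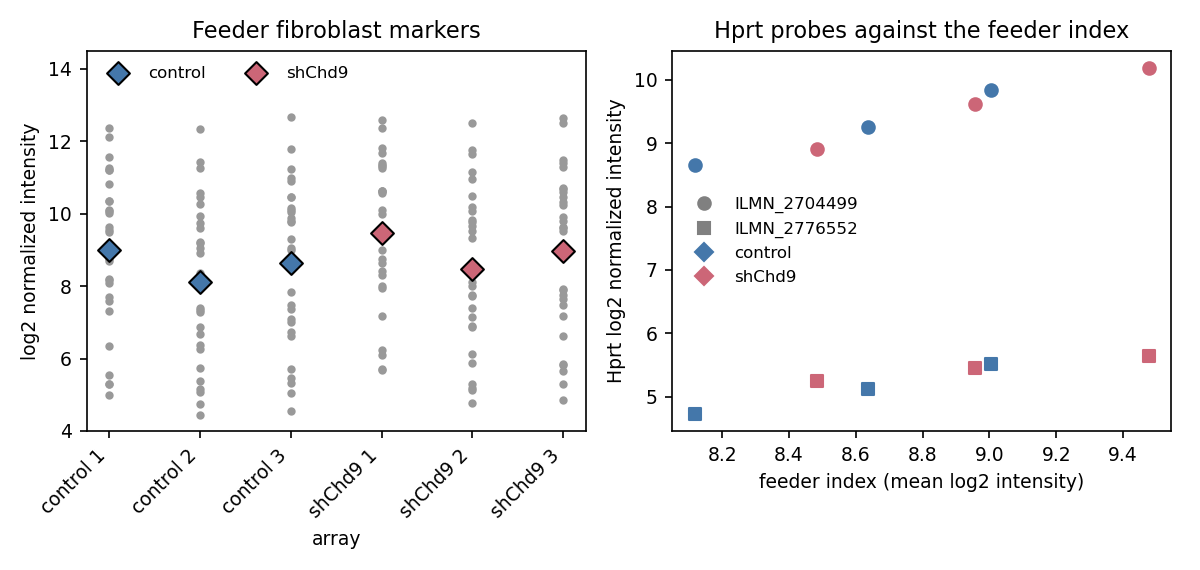
Left, log2 normalized intensity (vertical axis) of the 28 measured feeder fibroblast markers (grey points) on each array (horizontal axis), with their mean as a diamond, from 8.1 to 9.0 in control (blue) and from 8.5 to 9.5 in shChd9 (red). Right, log2 normalized intensity of both tested Hprt probes (circles and squares) against that mean, called the feeder index, where both probes are highest on the array with the highest index.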

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

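The block of paired arrays, the feeder covariate and the lists without feeder markers were chosen after seeing the data; all other alternatives were set beforehand. limma called 0 probes and 0 genes at an adjusted p under 0.05 under every alternative run, with between 663 and 2306 probes at an unadjusted p under 0.05. The smallest adjusted p of any probe was 0.0862, with an intensity trend and a robust prior. Chd9 stayed lower on both bright probes in each alternative, at log2 fold changes from -1.23 to -0.66 and from -1.26 to -0.68, the smallest without background correction. Its dim probe ranged from 0.11 to 0.56. Leaving out 1 array at a time, the bright probes ranged from -1.23 to -1.04 and from -1.26 to -1.03.

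The 8 lists that camera called with a preset correlation depended on the setting. It called 0 with an estimated correlation, 0 by fry and 0 with the feeder index as a covariate, where the feeder list itself cannot be tested. Leaving out 1 array at a time gave from 0 lists (without shChd9 replicate 1) to 13 (without shChd9 replicate 2), with 4 without control replicate 2. These fits have fewer samples, and the cause of the changed counts was not tested otherwise. Of the 8, 6 stayed without control replicate 1, 5 without shChd9 replicate 3, and all 8 without control replicate 3 or shChd9 replicate 2. All 8 were called, and no other list, under cyclic loess. The intensity trend and robust prior entered only limma's test of probes and genes, so they could not change the list calls. Median scaling added lysosome and autophagy, and no background correction, normexp without controls, the authors' processed values and the stricter filter added it and osteogenic regulators. Leaving out control replicate 3 added the first of these. Leaving out shChd9 replicate 2 added both, and also the interferon response, replication and S phase, and ribosome biogenesis. Leaving out control replicate 1 added the interferon response and the 2-cell-like state. Of the 8, 7 were called without the filter, 6 with array weights, 6 with the mean of a gene's probes, where lysosome and autophagy was added, and 7 without feeder markers in the other lists. In that last setting only the adhesion and transition list, among the 8, lost members. The feeder list was left whole and the others held no feeder markers, so it did not test their calls. At a threshold of 0.01, 4 of the 8 were called, and at 0.1 all 8 and lysosome and autophagy.

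The labels give no replicate numbers or shared batches, so whether the design paired the samples is not known. The pairs read from the data are also the order of the deposit. With the pairs read from the data as a block, 0 probes and 0 genes passed in limma, 1955 probes had an unadjusted p under 0.05, and camera called 11 lists with the preset and 0 with an estimated correlation. The 3 added were osteogenic regulators, lysosome and autophagy, and the 2-cell-like state (camera, adjusted p = 0.0209, and 0.417 with an estimated correlation), the last called also without control replicate 1 and without shChd9 replicate 3. The pairs were read from these values, so these p-values may be too small. Among the named genes, 22 values changed sign in some alternative, none of a gene that passed the test. Median scaling moved the median of all probes by 0.04, below 0.1. Signal over background limits dim probes, whose log2 fold changes shrink without background correction.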

Other observations

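The split and leave-one-out tests of the feeder difference, the leave-one-out values of the ratio over 476 genes, the splits of both probe counts and the differences within pairs were chosen only after the result was seen, and so was the rule that a value must lie beyond 1 SE of its bound to decide; the other tests here were written down before their values were known.

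Arrays of the same group differed by more than 2 log2 units in some genes. On control replicate 1 the acute phase gene Saa3 lay 2.47 above its group mean on the log2 scale, S100a8 2.05 and the matrix proteoglycan Lum 2.04, and on shChd9 replicate 1 the same genes lay 2.76, 2.29 and 2.12 above theirs. On control replicate 2 and shChd9 replicate 2 Saa3 lay at -2.51 and -2.88, Dcn at -1.58 and -1.82, and the lysozyme gene Lyz1 at 1.57 and 1.65. On the remaining array of each group the proliferin genes Prl2c2, Prl2c3 and Prl2c4, near-identical copies whose separate levels are uncertain, lay between 1.53 and 1.75 above the group mean. These genes were chosen from the 10 with the largest deviations on each array. Among the 28 feeder markers, 4 of which other lists hold too, the probes with the highest intensity in control samples were those of Ccn2 and Lgals1, at 12.37 ± 0.27 and 11.80 ± 0.56 in control and 12.51 ± 0.14 and 12.25 ± 0.51 in shChd9 samples (log2 intensity, mean ± SD, n = 3 each). Stem cells without feeders were not analysed here, so how many of the markers stem cells also express is open.

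The feeder markers and the lists that moved beside them form the first pattern, for which more feeder RNA in the shChd9 samples is a candidate explanation: 476 genes in no list that followed the feeder index within the groups had a mean log2 fold change of 0.22, a ratio of 0.703 to the shift their slopes predict, but from 0.457 to 0.668 with 1 array left out, on both sides of the bound of 0.5, and with all arrays normalized together the feeder difference of 0.386 came to 0.134 without shChd9 replicate 1, within its unpaired SE of 0.385, and to 0.343, 0.396 and 0.419 without each pair of the second pattern in turn. The mean of the 39 primitive endoderm, trophectoderm and Hox genes went from 0.26 to 0.13 ± 0.06 (SE) with the feeder index as a covariate. Its ratio was 0.481. The mean of the mitosis list went from -0.14 to -0.06 ± 0.04, a ratio of 0.394. Both ratios were too near the bound of 0.5 to decide. For other single lists no bound was set beforehand. The ratio was 0.360 for primitive endoderm, 0.641 for trophectoderm and 0.571 for Hox genes. The immediate early mean went from 0.18 to 0.13 ± 0.04, a ratio of 0.734. The p53 target mean went from 0.17 to 0.11 ± 0.12, a ratio of 0.659. For the 9 lower genes with the smallest p other than Chd9, the median was -0.96 with and without the covariate, a ratio of 0.998. Single genes moved both ways, Aurkc from -1.14 to -0.88 and Serpinb6c from -0.95 to -1.07. Genes picked for a small p vary little within groups, while the feeder index varied within groups by an SD of 0.45 and 0.50. Genes that follow the index could thus hardly be picked. Dilution of stem cell RNA alone would, however, lower stem cell genes by a like amount. In the same samples the 16 core pluripotency genes averaged -0.06 (8 higher, 8 lower) and the 18 naive ones -0.08 (7 higher, 11 lower). These values argue against dilution as the source of a fall as large as that of the 9 genes. Whether dilution added a smaller part stays open. More primitive endoderm cells stay open. The 6 measured genes taken beforehand as specific to that lineage had a median of 0.175, between the bounds of 0.1 and 0.2. With the covariate 3 were higher (Gata6 at 0.51, Sox17 at 0.31, Hnf4a at 0.11) and 3 lower (Dab2 at -0.12, Amn at -0.16, Sox7 at -0.24). Whether feeder cells also express them was not tested. An effect of Chd9 on these genes stays open as well, and the design does not separate it from slide position.

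A second pattern is that arrays deviated from their group means in pairs across the groups. Over genes, which are not independent replicates, the deviations of control 1, 2 and 3 correlated with those of shChd9 1, 2 and 3 at r = 0.41, 0.38 and 0.32. The other 5 pairings averaged between -0.19 and 0.06. Deviations from a group mean cancel within the group, so a high average for 1 pairing by itself lowers that of the others. A shared culture round or feeder batch is a candidate explanation. Pairs took 94.8% of the within-group variance of the feeder markers, at percentile 100 among 10000 random lists matched on level. The random lists hold genes that need not vary together, so any list of genes that do could rank high whatever its source. Any pairing takes some share of the within-group variance even where nothing is shared, and this one had the highest average correlation of the 6. A share by itself thus does not show a common source. Pairs took from 27.9% to 95.1% of the within-group variance of the other 35 lists, with a median of 73.2%. The highest, for the 2-cell-like state, marks no feeder cell, so which source the pairs shared stays open. Array brightness is not settled as a cause, since this pairing ranked 2 of the 6 by closeness of raw mean intensity. The pairing, 1 of 6 possible, is a hint from the data that is also the order of the deposit, and within these pairs the feeder list differed by 0.47, 0.37 and 0.32 (mean 0.386, SE 0.045, exact sign-flip permutation p = 0.25, the smallest 3 pairs allow), scores on the first principal component by -21.1, -16.7 and -17.3, and detected probes by -207, -185 and -247, with an SE that may be too small where pairs were read from such values.

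The splits take the 6 arrays as exchangeable, which does not hold if the pairs of the second pattern shared a source. The feeder difference of 0.386 was reached in 5 of the 10 splits, with 0.733 the highest other. The real split gave 0 probes at an adjusted p under 0.05 in limma, as did all 10, and 942 probes at an unadjusted p under 0.05, a number reached in 6 of the 10 splits, with 1804 the highest other. Camera called 8 lists, a number reached in 4 of the 10, with 16 the highest other. The 10 splits are too few for a share under 0.05. The split with 1804 probes set control 1, shChd9 1 and shChd9 3, the 3 arrays with the highest feeder index, against the rest, which points to a structure of the samples.

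The last pattern is that Hprt, often used as a reference gene, varied between arrays of a group by an SD of 0.59 and 0.64, while other Actb and Tbp probes reached 0.62 (ILMN_2846865) and 0.42 (ILMN_2454677) with a Pearson r with the feeder index of -0.52 and -0.17 (exact permutation p = 0.285 and 0.775, adjusted 0.777 and 0.865). Hprt transcript that comes mainly from the feeder cells is a candidate explanation, and both tested Hprt probes followed the feeder index over the 6 arrays, at a lowest Pearson r of 0.943. Probe ILMN_2704499 gave r = 0.985 (exact permutation p = 0.00139, adjusted 0.0236 over 17 relations) and Spearman's rho of 1 (exact permutation p = 0.00278, adjusted 0.0472), with r = 0.984 without the 2 arrays farthest from the median. Probe ILMN_2776552 gave r = 0.943 (exact permutation p = 0.00972, adjusted 0.0826) and rho of 0.943 (exact permutation p = 0.0167, adjusted 0.142), with r = 0.862 without those arrays. The permutations take the 6 arrays as exchangeable, which does not hold if the pairs of the second pattern shared a source. The p-values of these correlations may then be too small. The labels do not name the stem cell line, so whether its own Hprt gene is active was not tested.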
